A study of Mus musculus with 6 samples.

How the data were processed

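5C was performed on MEF, Rag2-deficient pro-B cells and CD43-negative resting splenic B cells with 2 libraries each, grouped by the titles in the labels. 5C anneals pairs of primers to the junctions of a 3C library, so that each count is the number of sequenced products of 1 forward and 1 reverse primer. The deposited files hold raw counts of valid read pairs per primer pair, with a read length of 42 per the file headers, and list only pairs with at least 1 read; pairs not listed were set to 0. The submitters' processing notes name Novoalign for alignment and mm9 as the genome build; the version of Novoalign is not given in the sources used here. The file headers record no correction for distance, primer strength or depth, and no molecular identifiers, so duplicates from amplification are counted and intervals and floors cover counting error only. A second numeric column holds the number 1 throughout and was not used.

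Depth was 20580457 to 24191175 valid pairs per library (83.5% to 92.3% of raw reads). A pair with 0 reads could hold up to 3 reads of the total. Reads between chromosomes made up 0.554% of pro-B replicate 1 (95% Wilson interval 0.550 to 0.557) and 3.41% of resting B replicate 2 (3.40 to 3.42). The 10 pairs with the most reads held 23.1% to 39.9% of the Igh reads. Counts of replicates differed by more than sampling noise (chi-square per degree of freedom of 327 in pro-B cells, 144 in MEF and 72.4 in resting B cells), so each library was counted as 1 replicate.

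Fragment coordinates are those in the primer names (mm9). No mm9 annotation was used, so single V genes are not named. Regions and 3 landmarks (intronic enhancer, the 3′ part of the 3′RR, IGCR1) were set from approximate textbook positions before the data were examined, and each is described by the fragments it covers; fragments were assigned by position, so a region's edge is approximate. Pairs of cis fragments with at least 10 reads in at least 2 libraries were tested with edgeR (version 4.0.16, R 4.3.3): TMM scaling over all tested cis pairs, a quasi-likelihood fit of all 6 libraries with cell type as the only term, and Benjamini-Hochberg adjustment over Igh pairs and over desert pairs separately, with a threshold of 0.05. Reads summed over each of the 55 pairs of regions were tested in the same way with the same scaling, and so were reads of each Igh fragment with the desert, with TMM over fragments. Pairs holding a landmark fragment were also adjusted over the list alone. SE is the log2 fold divided by the square root of the F statistic.

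The named pairs were chosen by a rule set before the data were examined: per comparison, up to 10 rising and 10 falling pairs in order of p among those past the threshold, over 100 kb apart, with both libraries of one group above both of the other, and with no fragment used more than once per direction. Region pairs past the threshold were named where they were among the 5 largest folds in a direction or joined the constant region, 3′RR or D-J region to a V region, and each landmark was named with up to 3 partners per direction. The text describes some of the named pairs, and the plot of named primer pairs shows all of them.

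Loops were pairs over 50 kb apart with a standardised residual of at least 2 in both replicates, from a quasi-Poisson model per library with a natural spline of log separation (4 degrees of freedom) and forward and reverse primer effects. Insulation was the mean log2 ratio of observed to expected counts, with 1 added to each, across a fragment boundary within 200 kb and over at least 20 pairs, and a minimum, the lowest score within the window on either side, counted where both replicates had one within 50 kb. Shares of long-range reads were compared by an exact two-sided permutation test, added after the shares were seen.

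The test was run on simulated data before the real counts: counts drawn for the 11940 Igh pairs from the real means, with 100 pairs changed 4-fold and 100 changed 16-fold. For pro-B over MEF it recovered 2% of the 4-fold and 55% of the 16-fold changes, for resting B over MEF 4% and 50%, and for resting B over pro-B 7% and 54%, with 1, 1 and 2 false calls. Changes under 4-fold in single pairs are therefore mostly out of reach. The simulated counts shared 1 dispersion trend, fitted to the real counts, across all cell types. The numbers of false calls therefore do not cover the unequal spread of the cell types in the real counts. In a simulated library the loop model recovered 46 of 50 planted 20-fold pairs among 12038 and called 87 pairs that were not planted; loops in the text had to pass in both replicates, which that simulation did not cover.

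Alternatives were total cis reads or gene desert reads as library size, DESeq2's size factors and its Wald test (version 1.42.0), no filter or at least 50 reads, only the 4 libraries compared, the replicate number as a block, an offset removing each library's lowess trend (span 0.3) of log count over separation, pairs over 50 kb alone, and leaving out each library in turn, where the remaining library of a group is assumed to vary like the others. Chosen after seeing the data were the region test on mean log2(CPM + 1) with limma (version 3.58.1), the omission of FOR 31 with REV 545, and a log-linear loop model. Gene desert scaling moved the median log2 fold of all Igh pairs to 0.45 for resting B over MEF, 0.29 for resting B over pro-B and 0.19 for pro-B over MEF, and total reads moved it to 0.21, 0.28 and -0.03. Distance correction moved it to -0.06, -0.46 and 0.43. Folds are to be read relative to these shifts. The gene table supplied as a reference is of GRCm38.p6, another build, so none of its coordinates were used. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots. Pairs of 2 forward or 2 reverse primers, which the design does not use, were left out of the comparisons.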

Results

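Chromosome conformation capture carbon copy (5C) was used to count ligation products between HindIII restriction fragments across the mouse immunoglobulin heavy chain (Igh) locus on chromosome 12 and, as a control, across a gene desert on chromosome 5. The comparison was between 3 cell types, with 2 biological replicates each per the series description. Mouse embryonic fibroblasts (MEF) do not use the locus. Pro-B cells from bone marrow lacked Rag2, which is needed for V(D)J recombination, so their Igh alleles were unrearranged, and they had been expanded in culture with an interleukin. CD43-negative resting B cells came directly from the spleen and carry rearranged alleles. Cell type and culture history went together in this design and cannot be separated. The 112 forward and 113 reverse primers gave 12656 possible Igh pairs between positions 114339456 and 117350186 (mm9). Valid read pairs per library ranged from 20580457 in resting B replicate 2 to 24191175 in MEF replicate 1, and 91.3% to 93.4% of them joined 2 Igh fragments. In both replicates of a cell type, 12071 Igh pairs were detected in MEF, 11850 in resting B cells and 10815 in pro-B cells. Across primer pairs, which are not independent replicates, the log2 counts of replicates correlated with Pearson's r of 0.94 in resting B cells, 0.905 in MEF and 0.725 in pro-B cells. Pro-B replicate 2 stood apart: 1641 of its Igh pairs had 0 reads, against 448 in pro-B replicate 1, and pro-B replicate 1 correlated at 0.872 with MEF replicate 1.

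Pro-B cells were compared with MEF to ask how the unrearranged locus is folded in B-cell progenitors, which here lack Rag2 and cannot recombine it. In summed reads, contacts of the 3′ regulatory region (3′RR) and its 3′ flank with the D-J region and the proximal V genes were higher in pro-B cells. The 3′RR, a cluster of enhancers and CTCF sites covered by fragments from 114434637 to 114480873, contacted the D-J region, which holds the intronic enhancer with the J and D segments (114656273 to 114691293), more often in pro-B cells, by 2.30 ± 0.28 on the log2 scale (SE, n = 2 libraries per group; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000886). Its contacts with the constant region genes (114486613 to 114656272) were higher by 1.64 ± 0.33, and those with the proximal V genes (114809751 to 115096374) by 1.63 ± 0.29 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0144 and 0.00866). The flank 3′ of the regulatory region contacted the D-J region (1.17 ± 0.26) and the proximal V genes (1.11 ± 0.29) more often (edgeR, adjusted p = 0.0227 and 0.0456). With each primer pair counted once on the log scale, the 3′RR folds were smaller, at 0.90 with the D-J region, 0.46 with the constant region and 0.87 with the proximal V genes. Those of the 3′ flank were 0.52 with the D-J region, which no longer passed (limma, adjusted p = 0.057), and 0.41 with the proximal V genes. These were the 5 of 55 region pairs past the threshold of 0.05, and none passed as lower in sums, while with mean logs 10 passed as higher and 12 as lower. The 12 were the constant region with V-D (-0.67), the 5′ flank (-0.57), D-J (-0.49), and proximal (-0.45), middle (-0.38), near distal (-0.29) and far distal V (-0.45), D-J with proximal V (-0.63), V-D (-0.62) and middle V (-0.35), the 3′ with the 5′ flank (-0.60), and proximal with far distal V (-0.28). No pair of V regions passed in sums. Reads to the gene desert of the 8 fragments of the 3′RR had a median log2 fold of 0.69 in pro-B cells over MEF, with 3 below 0. Medians were 0.10 for the constant region, -0.44 for D-J and -0.03 for proximal V fragments, and no fragment passed. A part played by copies or recovery of the 3′RR fragments was therefore not excluded. In sums, the 3′RR and D-J region shared 4624 and 3282 CPM in pro-B replicates 1 and 2 against 856 and 751 in MEF. The median over their 52 primer pairs of pro-B replicate 1 over the MEF mean was 0.43 on the log2 scale. That was below the 0.59 between the MEF libraries, but both values were scaled to total Igh reads without TMM. Over all Igh pairs the medians of MEF replicates 1 and 2 were 62 and 104 reads, with TMM factors of 0.728 and 1.22. The 0.59 therefore holds an offset between the MEF libraries and does not bound the spread at these pairs. No single primer pair of the 11940 tested passed in edgeR's quasi-likelihood test. Of these, 1094 had an unadjusted p under 0.05, and DESeq2 called 167 higher and 139 lower. All 5 calls held without either pro-B replicate, and 4 of them were lost without MEF replicate 1, 5 without MEF replicate 2 and 2 without either resting B replicate. In counts, 19 higher and 2 lower passed without pro-B replicate 1, and 11 and 6 without pro-B replicate 2. The counts were 1 and 0 without MEF replicate 1, 0 and 0 without MEF replicate 2, and 3 and 1 without either resting B replicate. Scaling to total reads gave 2 higher and 1 lower, and scaling to gene desert reads gave 1 higher and 0 lower.

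Resting B cells were compared with MEF to ask how the folding of the locus differs between mature B cells and cells outside the lineage. Contacts within each V region fell in resting B cells. Contacts among the 3′ flank, constant and D-J regions rose, and so did those of the constant region with the distal V genes. Of the 4630 tested primer pairs with both fragments in V regions, 79.4% had a fold below 0, with a median of -0.96 on the log2 scale. Of the 958 pairs with both fragments in the 3′ flank, 3′RR, constant or D-J regions, 39 rose and 3 fell, with a median of 1.51.

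In sums over region pairs, the flank 3′ of the 3′RR (114339456 to 114420752) gained contacts with the D-J region (2.53 ± 0.28, adjusted p = 0.000272), the constant region (2.42 ± 0.27) and the far part of the distal V genes (116539430 to 117190694; 2.25 ± 0.30). The 3′RR gained contacts with the D-J region (2.21 ± 0.27), the far distal V genes (1.33 ± 0.30) and the proximal V genes (0.80 ± 0.28). With each primer pair counted once on the log scale, the fold with the proximal V genes was 0.13 (limma, adjusted p = 0.38). Its rise of 2.41 ± 0.60 with the nearer part of the distal V genes (115723372 to 116439886) rested on 1 primer pair, FOR 31 with REV 545, which took 594468 and 1520284 reads in the resting B libraries. Without that pair the fold was -1.16 and passed as a fall (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.021). With each primer pair counted once it was 0.52, a rise (limma, adjusted p = 0.00464), so the direction was not settled. The constant region rose with the near and far distal V genes by 1.04 ± 0.31 and 1.21 ± 0.24, and the D-J region rose with the far ones by 0.83 ± 0.29, or 0.16 with each pair counted once (limma, adjusted p = 0.438). Contacts fell within the 3′RR (-2.36 ± 0.54; the reads of its fragments FOR 23 and REV 24 to the gene desert had folds of -1.65 ± 0.47 and -1.71 ± 0.58, neither past the threshold), within the near distal V genes (-1.43 ± 0.49), within the far distal V genes (-1.41 ± 0.48), within the V-D intergenic region (-1.37 ± 0.36), and within the middle V genes from 115139357 to 115709849 (-1.36 ± 0.47). In all, 18 region pairs rose and 9 fell (edgeR quasi-likelihood with Benjamini-Hochberg over 55 region pairs; errors are SE, n = 2 libraries per group). Scaling to gene desert reads left 11 higher and 3 lower and scaling to total reads 16 and 5, and no called region pair changed sign under either scaling. Distance correction left 10 higher and 2 lower. Counts without 1 library were 7 and 1 (MEF replicate 1), 9 and 8 (MEF replicate 2), 14 and 1 (resting B replicate 1), 12 and 0 (resting B replicate 2), and 27 and 16 (either pro-B replicate). None of the falls within a V region passed without either resting B replicate. With each pair counted once, further folds shrank: 1.77 and 1.42 (3′ flank with D-J and far distal V), 0.91 and 0.46 (3′RR with the same), 0.68 and 0.64 (constant region with near and far distal V), -1.26 within the 3′RR, and -0.65, -1.16 and -0.95 within the near distal, far distal and middle V genes.

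**Figure D1:**
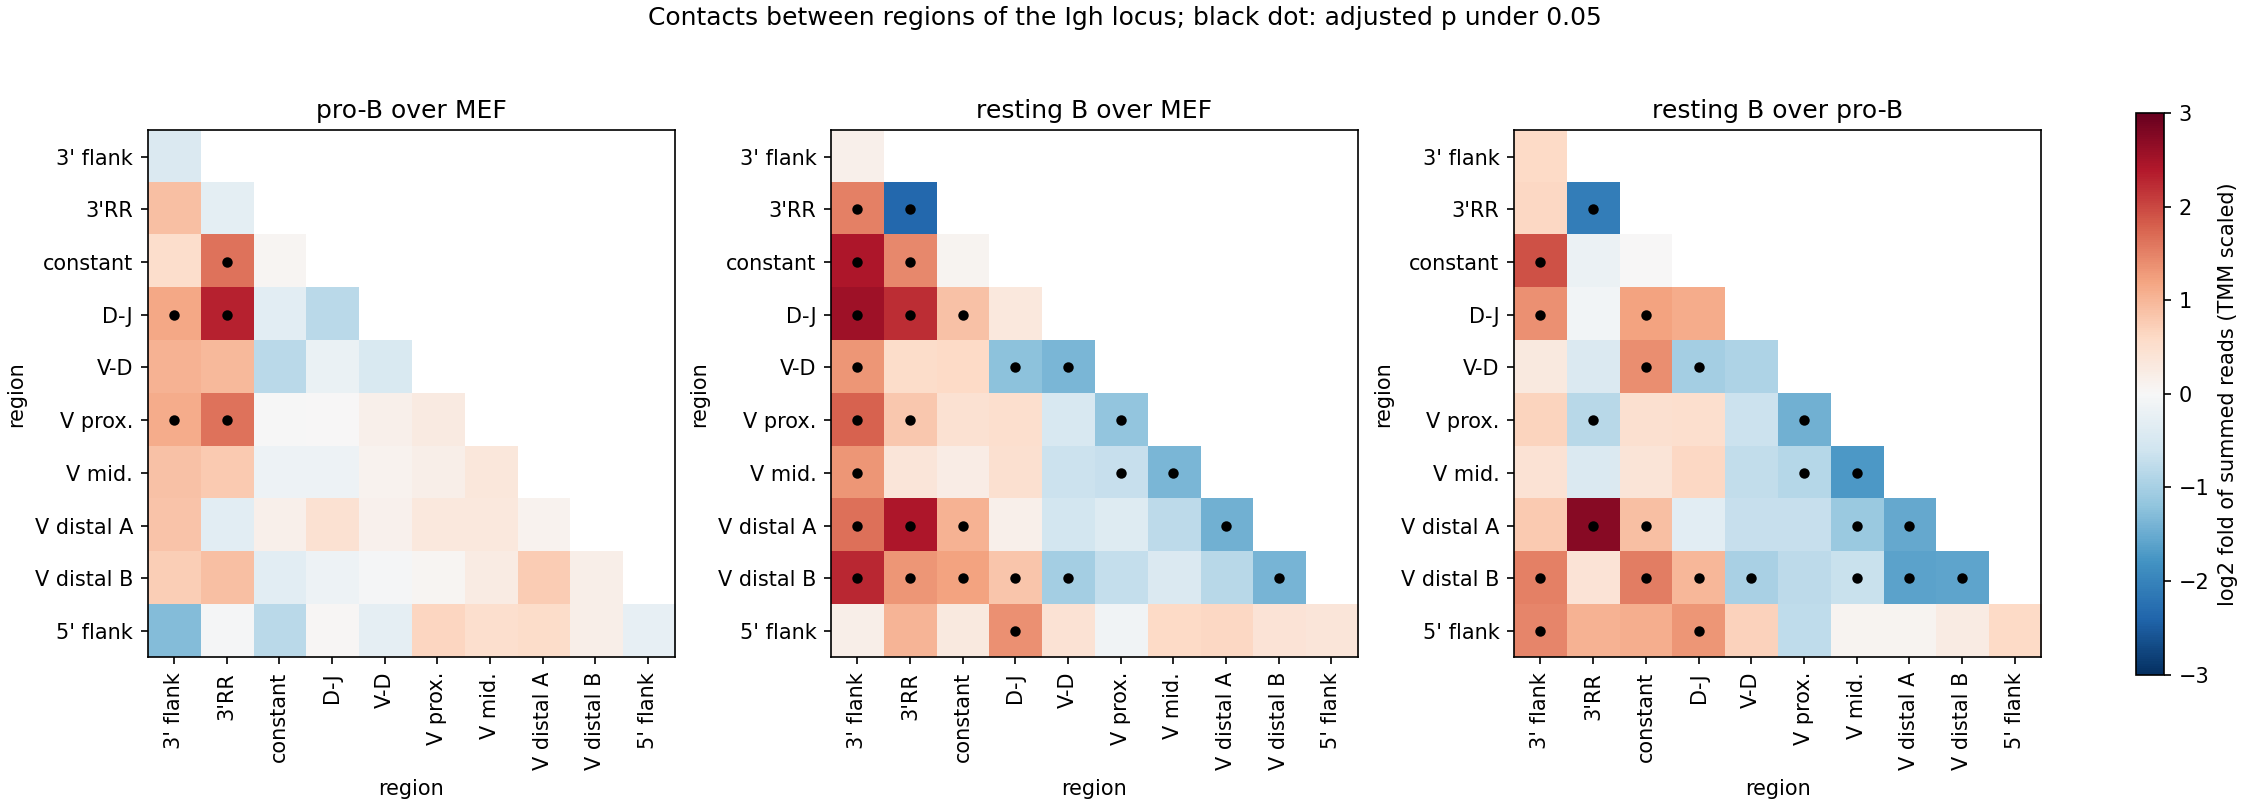
Log2 fold of summed, TMM-scaled reads for each of the 55 pairs of regions, with regions on both axes ordered from the 3′ to the 5′ end of the locus and 1 panel per comparison; dots mark adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg). In both resting B panels contacts within each V region fell, while those of the far distal V genes with the constant region rose (1.21 over MEF and 1.52 over pro-B). In pro-B cells against MEF no region pair passed the threshold as a fall in sums.

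Single primer pairs rose and fell as well. The fragment at 115816276 to 115822016 (FOR 415) in the near distal V genes and the intronic enhancer fragment at 114664824 to 114667095 (REV 81), 1153 kb apart, gave 7619 and 7178 reads in resting B cells against 188 and 375 in MEF, a log2 fold of 4.72 ± 0.45 (SE, n = 2; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0383). Fragments next to the enhancer rose with the 3′ end of the constant region: FOR 78 (114659959 to 114662158) with REV 35 (114493852 to 114496828) by 4.01 ± 0.38, and FOR 80 (114664064 to 114664823) with REV 33 (114486613 to 114491122) by 4.11 ± 0.47. A fragment of the 5′ flank, FOR 837 (117317889 to 117319542), rose with REV 435 in the near distal V genes (115877939 to 115880010), 1440 kb away, by 5.77 ± 0.61. Among the falling pairs, all 6 named ones joined 2 V fragments. FOR 769 (117102069 to 117108895) with REV 464 (115993659 to 116000828) gave 19 and 8 reads in resting B cells against 444 and 491 in MEF (-5.21 ± 0.67), and FOR 233 (115211655 to 115215965) with REV 260 (115327864 to 115330485) changed by -4.41 ± 0.50. Of 11940 pairs, 44 rose and 46 fell in edgeR's quasi-likelihood test. Among the 613 tested pairs within 50 kb, 2 rose and 22 fell, and among the 8147 over 500 kb apart, 5 rose and 9 fell. Without any 1 of the MEF or resting B libraries 0 pairs passed. Without pro-B replicate 1 the counts were 1617 higher and 1670 lower and without pro-B replicate 2 they were 1642 and 1714. DESeq2 called 756 and 889, and with pairs over 50 kb alone 0 passed.

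**Figure D2:**
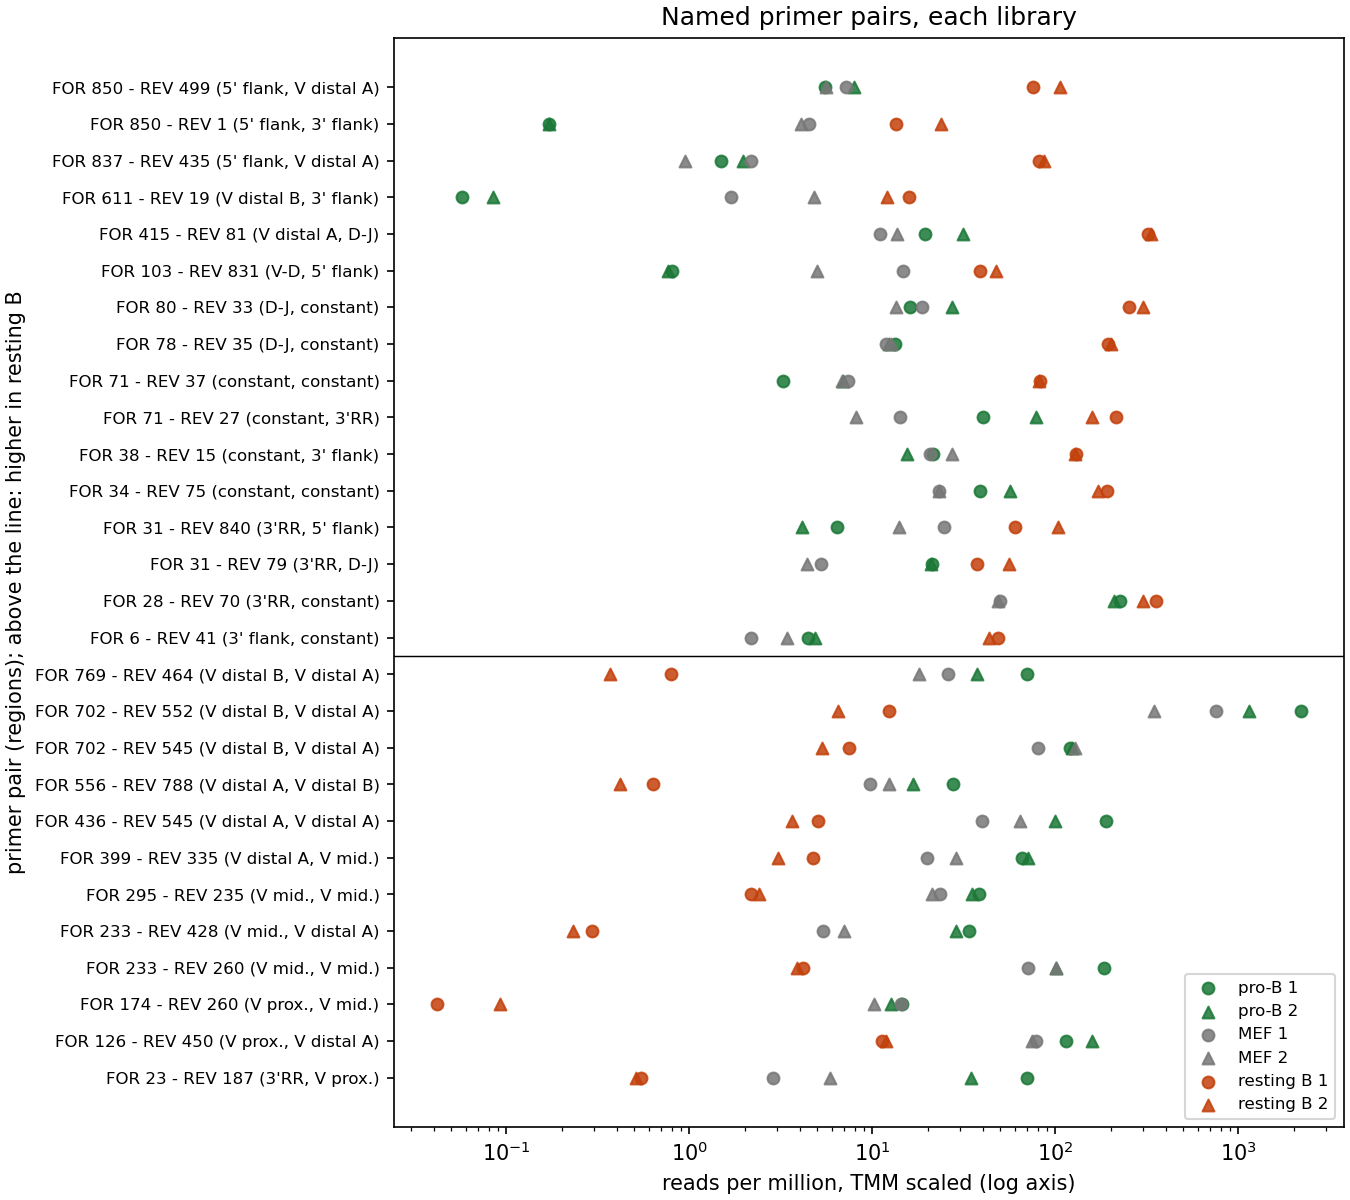
CPM, TMM scaled, on a log axis, for each library of the primer pairs named by the fixed rule in the comparisons of resting B cells with MEF and with pro-B cells (rows; circles are replicate 1, triangles replicate 2). Pairs above the line were higher in resting B cells and pairs below it lower, and both resting B libraries lie outside the libraries they were compared with; for FOR 415 with REV 81 they held 319 and 332 CPM.

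Resting B cells were compared with pro-B cells to ask what changes in the locus between the progenitor and the mature stage. Contacts between V genes were lower in resting B cells, and most primer pairs within the constant side or joining it to V genes were higher. The 3′RR, counted in the constant side, was mixed. Past the threshold, 0 pairs rose and 4 fell within it, and 3 and 6 with the D-J region. With the proximal and middle V genes 0 rose, and 8 and 20 fell. With the constant region 12 rose and 3 fell, and with the 3′ flank 6 and 1. In this comparison 14.1% of the gene desert control pairs passed (18 higher, 13 lower), against 7.90% of the Igh pairs. Passing the threshold therefore does not by itself mark a change particular to the locus. Of 4630 tested pairs inside the V array, 502 fell and 10 rose, with a median log2 fold of -1.03. Of 958 pairs on the constant side, 134 rose and 24 fell, and of 4141 pairs joining the constant side to V genes, 117 rose and 50 fell.

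In region sums, contacts fell within the 3′RR (-2.07 ± 0.53), within the middle V genes (-1.71 ± 0.47), between the near and far distal V genes (-1.61 ± 0.41), and within the far (-1.59 ± 0.48) and near (-1.54 ± 0.49) distal V genes, and the 3′RR lost contacts with the proximal V genes (-0.83 ± 0.28). Reads of the 3′RR fragments FOR 23 and REV 24 to the gene desert also fell past the threshold, with log2 folds of -2.46 and -2.75. The 3′ flank rose with the constant region (1.90 ± 0.27, adjusted p = 0.00318), the far distal V genes (1.5 ± 0.29) and the 5′ flank (1.48 ± 0.48). The constant region rose with the near and far distal V genes by 0.89 ± 0.31 and 1.52 ± 0.24, and the D-J region with the far ones by 0.99 ± 0.29. The rise of the 3′RR with the near distal V genes (2.72 ± 0.61) again rested on FOR 31 with REV 545: it was -0.37 without it (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.355) and 0.07 with each pair counted once (limma, adjusted p = 0.54). In all, 11 region pairs rose and 12 fell (edgeR quasi-likelihood with Benjamini-Hochberg; SE, n = 2 per group), with 13 and 6 after scaling to total reads and 5 and 5 after scaling to the gene desert. After correction for the distance decay of each library, the folds of the far distal V genes with the 3′ flank, constant and D-J regions became -0.23, -0.00407 and -0.32, and those of the 5′ flank with the 3′ flank and D-J region -0.79 and -0.71. With each pair counted once the falls were -1.14 within the 3′RR, -0.80, -1.11 and -0.65 within the middle, far and near distal V genes and -0.66 between the distal ones, and the rises of the far distal V genes with the constant and D-J regions were 1.10 and 0.47. Counts without 1 library were 12 higher and 13 lower (pro-B replicate 1), 22 and 16 (pro-B replicate 2), 9 and 9 (either MEF replicate), 9 and 0 (resting B replicate 1) and 5 and 0 (resting B replicate 2).

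The primer pair with the most reads among the named losses joined FOR 702 (116864979 to 116868374) in the far distal V genes to REV 552 (116364360 to 116366864) in the near ones, 501 kb apart. It held 38314 and 26864 reads in pro-B cells, 12820 and 9418 in MEF, and 293 and 140 in resting B cells, a log2 fold of -7.47 ± 0.75 for resting B over pro-B cells (SE, n = 2; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0189). FOR 23 in the 3′RR (114441222 to 114447060) with REV 187 in the proximal V genes (115061883 to 115074065) gave 1222 and 814 reads in pro-B cells against 13 and 11 (-6.61 ± 0.74). The reads of FOR 23 to the gene desert also fell, by 2.46 on the log2 scale. FOR 233 with REV 428 (115848051 to 115855284) changed by -6.86 ± 0.68. The reads of REV 428 to the gene desert fell by 2.52. FOR 174 (115011448 to 115018809) with REV 260 gave 255 and 296 reads in pro-B cells and 1 and 2 in resting B cells. Pairs higher in resting B cells included FOR 78 with REV 35 (3.95 ± 0.38), FOR 415 with the intronic enhancer fragment (3.68 ± 0.43) and pairs spanning the whole locus: FOR 850 (117345114 to 117346619) with REV 1 (114339456 to 114341053), 3006 kb apart, gave 323 and 514 reads in resting B cells, 77 and 112 in MEF, and 3 and 4 in pro-B cells. FOR 103 in the V-D region (114747437 to 114750051) with REV 831 in the 5′ flank (117305833 to 117307899) rose by 5.78 ± 0.75. Of 11940 pairs, 327 rose and 616 fell. The split changed to 456 and 349 with gene desert scaling, 416 and 406 with total reads, and 279 and 832 with distance correction. DESeq2 called 1303 and 1601. No pair passed without any 1 of the MEF or resting B libraries or with the 4 compared libraries alone. The counts were 3328 and 2210 without pro-B replicate 1 and 1804 and 2033 without pro-B replicate 2.

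The intronic enhancer, a B-lineage enhancer between the J segments and the first constant gene, had more contacts in resting B cells with most partners. Its fragment REV 81 had a median log2 fold over 111 partners of 1.65 against MEF and 1.73 against pro-B cells, with 7 and 5 partners below 0. The gain was highest with the 3′ flank (median of 4.16 over MEF, 8 partners), followed by the 3′RR (2.82), the constant region (1.97), and the far and near distal V genes (1.84 and 1.83). It was lowest with the V-D region (0.208) and the D-J region (0.415), with 0.852 for the middle V genes. Partners in the 3′RR (FOR 31, 114477117 to 114480873) and the constant region (FOR 34, 114491123 to 114493851) rose by 3.93 ± 0.44 and 3.72 ± 0.43 over MEF (SE, n = 2 per group; edgeR quasi-likelihood with Benjamini-Hochberg over all pairs, adjusted p = 0.0383 for both). Against pro-B cells, FOR 36 (114496829 to 114501530) and FOR 34 rose by 3.48 ± 0.43 and 3.17 ± 0.42. Over all pairs 5 partners rose against MEF and 20 against pro-B cells. Adjusted over the list alone 37 and 38 rose, and none fell in either comparison. Against MEF the number rising, adjusted over the list alone, was 80 without either pro-B replicate, 4 without either MEF replicate, 18 without resting B replicate 1 and 5 without resting B replicate 2. Against pro-B cells it was 84 and 60 without pro-B replicates 1 and 2, 18 without MEF replicate 1, and 14 and 7 without resting B replicates 1 and 2. Between pro-B cells and MEF 0 of 111 partners passed edgeR's quasi-likelihood test, with 19 at an unadjusted p under 0.05. Adjusted over the list alone, DESeq2 called 7 higher and 5 lower. By edgeR 16 and 46 passed without pro-B replicate 1, and 13 and 2 without pro-B replicate 2.

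**Figure D3:**
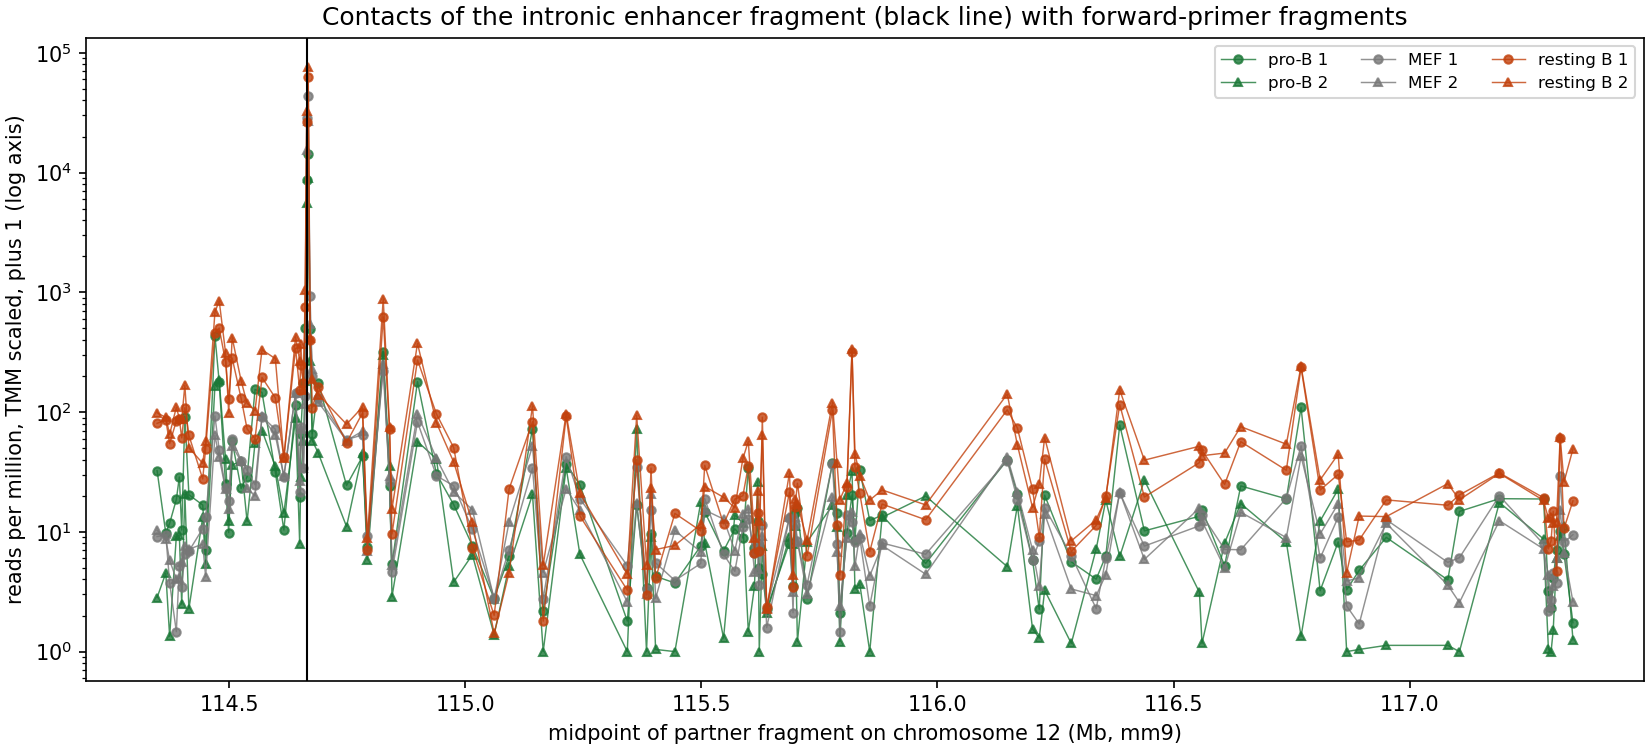
TMM-scaled CPM plus 1 (log axis) between the intronic enhancer fragment and each forward-primer fragment, against the partner's midpoint on chromosome 12 in Mb; lines join the partners of 1 library, and the black line marks the enhancer fragment. Resting B libraries lie above the others at most partners, with a median log2 fold of 1.65 over MEF.

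The fragment at IGCR1 (REV 94, 114722112 to 114723013), a pair of CTCF sites that separates D from V segments, had lower counts in resting B cells. V(D)J recombination removes DNA between the joined segments, where this fragment lies, and resting B cells carry rearranged alleles. Reads of the 5 V-D fragments to the gene desert had median log2 folds of -0.25 against MEF and -0.16 against pro-B cells. In these comparisons 5 and 3 of them lay below 0, so loss of DNA was not separated from changed folding. The median log2 fold of REV 94 over 106 partners was -1.77 against MEF and -1.97 against pro-B cells. Adjusted over the list alone, 12 partners fell against MEF and 37 against pro-B cells and none rose (1 and 18 over all pairs; edgeR quasi-likelihood with Benjamini-Hochberg). At an unadjusted p under 0.05 there were 40 and 53 partners in either direction, and DESeq2 called 3 higher against MEF. With gene desert scaling the falling partners were 2 and 6. With FOR 117 in the V-D region (114791568 to 114794187) it gave 8 and 2 reads in resting B cells, 207 and 279 in MEF, and 311 and 310 in pro-B cells, a log2 fold of -5.65 ± 0.87 over MEF (SE, n = 2; edgeR, adjusted p = 0.0467), and with FOR 84 in the D-J region (114670120 to 114672758) it changed by -4.05 ± 0.50 against pro-B cells. Without 1 library the falling partners against MEF were 46 and 44 (pro-B replicates 1 and 2) and 0 (each MEF or resting B replicate). Against pro-B cells they were 7 and 5 without MEF replicates 1 and 2 and 0 without either resting B replicate. Without pro-B replicates 1 and 2, 7 and 7 partners rose against MEF and 10 and 1 against pro-B cells.

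The 4 fragments from 114441222 to 114465908, in the 3′ part of the 3′RR, had a median fold of 1.07 in pro-B cells over MEF, and over all pairs none of their 414 pairs passed edgeR's quasi-likelihood test (80 with an unadjusted p under 0.05; adjusted over the list alone DESeq2 called 44 higher and 2 lower). Their reads to the gene desert had folds of 0.81 ± 0.46 (FOR 23), 1.05 ± 0.57 (REV 24), -0.03 ± 0.55 (FOR 25) and 0.56 ± 0.43 (REV 27), none past the threshold, beside V medians of 2.14, 1.13, 1.51 and 1.10. Against pro-B cells, resting B cells had fewer contacts of FOR 23 and REV 24 with V genes, and both fragments also lost reads to the gene desert. Adjusted over the list alone, 17 of 414 pairs were higher in pro-B cells than in MEF and none was lower, and the largest named gains joined REV 27 (114459545 to 114465908) to FOR 78 and FOR 76 (114656273 to 114658750) in the D-J region, with log2 folds of 4.31 ± 0.42 and 4.28 ± 0.42 (SE, n = 2). Over all pairs neither passed (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0923 for both). Resting B cells also exceeded MEF for REV 27 with FOR 78 (3.96 ± 0.41) and FOR 80 (4.63 ± 0.59). Over the 414 pairs 18 rose and 10 fell against MEF adjusted over the list alone, with a median of -0.06, and 1 and 6 of them had a V partner. Without resting B replicates 1 or 2 none passed. Without MEF replicates 1 and 2, 0 and 3 rose and 2 and 6 fell, and without pro-B replicates 1 and 2, 89 and 95 rose and 44 and 49 fell. Against pro-B cells, 66 of the 414 pairs fell and 17 rose adjusted over the list alone, and 50 of the falling pairs had a V partner; over all pairs 34 fell and 9 rose. Of those 50, 27 belonged to FOR 23 and 20 to REV 24, whose reads to the gene desert fell by 2.46 and 2.75 where their V medians were -3.92 and -2.90. FOR 25 (114449888 to 114450784) had 3, and REV 27 had none and a V median of 0.05. The steepest falls lay inside the 3′RR, where FOR 23 with REV 24 (114447061 to 114449887) held 77 and 43 reads in resting B cells against 8890 and 6296 in pro-B cells (-7.21 ± 0.68). For pro-B over MEF 55 pairs were higher and 37 lower without pro-B replicate 1, and 68 and 7 without pro-B replicate 2. The higher pairs numbered 0 and 2 without MEF replicates 1 and 2, and 7 without either resting B replicate, with 0 lower. For resting B against pro-B cells the falling pairs numbered 127 and 121 without pro-B replicates 1 and 2, 15 and 17 without MEF replicates 1 and 2, and 0 without either resting B replicate.

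Median read counts fell with genomic separation up to 1000 kb in every library. From 1000 to 2000 kb to 2000 to 3100 kb they went on falling in pro-B cells (35 to 26 and 56 to 35 reads), stayed level in MEF (38 to 37 and 61 to 62), and were higher in resting B cells (64 to 94 and 60 to 88). The median count at 20 to 50 kb was 8.63 and 7.31 times that at 2000 to 3100 kb in the resting B libraries, 15.0 and 13.8 times in MEF, and 21.0 and 17.1 times in pro-B cells. The share of reads over 500 kb among Igh reads over 50 kb was 54.3% ± 7.17 in resting B cells, 44.6% ± 2.42 in MEF and 43.2% ± 9.50 in pro-B cells (SD, n = 2 each). The higher share of resting B cells rested on FOR 31 with REV 545: without that pair it was 43.6% ± 1.67, against 43.6% ± 1.82 in MEF and 42.3% ± 8.60 in pro-B cells. In exact two-sided permutation tests of the shares with all pairs, p was 0.333 for resting B against MEF, 0.667 against pro-B cells and 1 for pro-B against MEF, and 0.333 is the smallest p that 2 libraries per group allow.

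**Figure D4:**
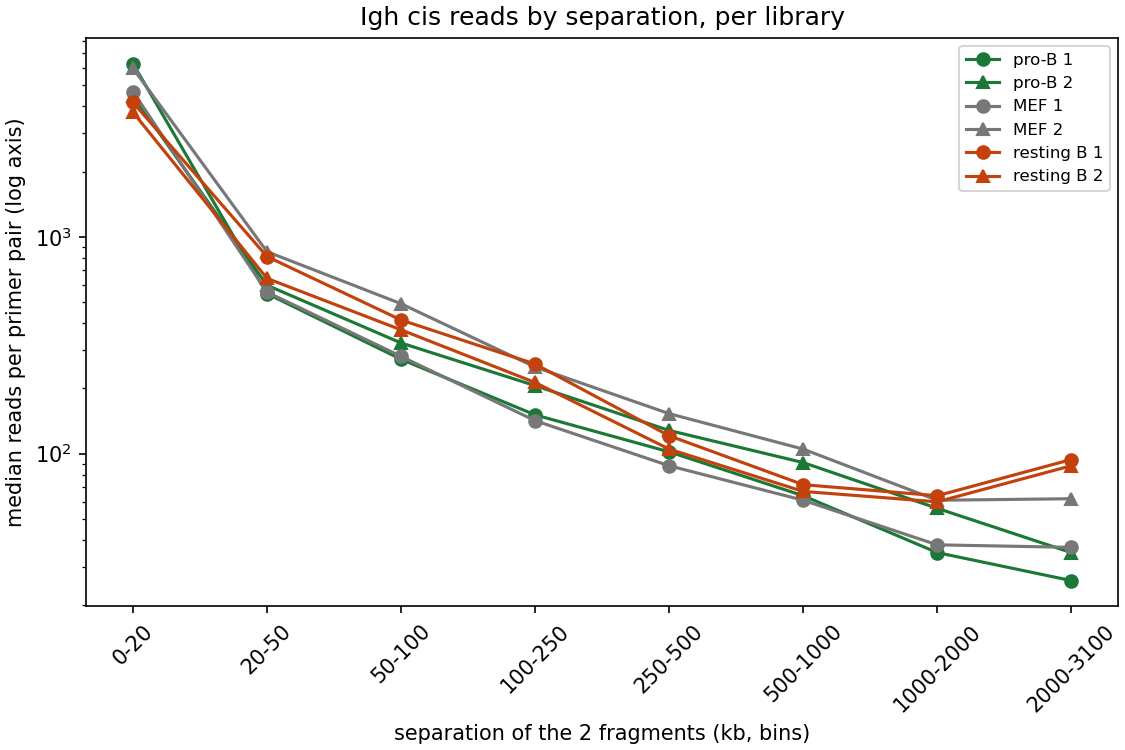
Median reads per Igh primer pair (log axis) in bins of fragment separation in kb, 1 line per library. Beyond 2000 kb the resting B libraries had medians of 94 and 88 reads, above MEF (37 and 62) and pro-B cells (26 and 35).

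Pairs far above the count expected from separation and primer strength were called as loops where both replicates passed, the criterion the series description sets for an interaction. Resting B cells had 93, pro-B cells 56 and MEF 54. If calls fell independently in the replicates, 1.17, 0.497 and 0.388 would pass in both. Model errors that recur in each library would break that assumption, so the excess does not count true loops. Of the 54 in MEF, 40 were also called in pro-B cells. The count for resting B cells depended on the model, at 9 with separation alone and 146 with a log-linear model, so the order of the cell types was not settled. The pairs with the highest residuals, chosen after their values were seen, included FOR 31 with REV 545 in resting B cells and FOR 702 with REV 552 in pro-B cells and MEF. FOR 451 with REV 300 was called in all cell types from as few as 56 reads in resting B replicate 1. There the primers gave 79 and 325 reads with all partners, and in pro-B replicate 2 they gave 45720 and 47176. The cause of these calls was not tested.

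Minima of insulation, where few contacts cross a fragment boundary within 200 kb, were found in both replicates at 7 places in pro-B cells, 6 in MEF and 5 in resting B cells. A minimum at 114449405, inside the 3′RR, appeared in both replicates of pro-B cells and MEF, with scores of -0.63 and -2.10 and of -0.60 and -0.50. Resting B cells scored -0.18 and 0.17 there, below the next boundary on either side, though it did not count as a minimum of both replicates. At 117028873, in the far distal V genes, scores were low in each library (-1.63 and -1.51 in MEF, -1.34 and -1.26 in resting B cells, -1.56 and -2.38 in pro-B cells), though it counted as a minimum of both replicates in MEF and resting B cells alone. With a 300 kb window pro-B cells had 2, MEF 4 and resting B cells 4, so the number of minima was not stable.

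Reads joining an Igh fragment to the gene desert on the other chromosome do not join 2 fragments of the locus. They were taken as a measure of copy number and fragment recovery. That premise was not tested, and other differences between cell types or libraries could change these reads. Against MEF, V fragments lay slightly lower in resting B cells, with medians of -0.13 (proximal), -0.18 (middle), -0.11 (near distal) and -0.16 (far distal), and the constant and D-J regions slightly higher, at 0.26 and 0.25. Of 224 fragments only REV 129 in the proximal V genes (114836439 to 114838819), named after its value was seen, fell (-3.85 ± 0.74; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0247), and it did not pass without either MEF replicate (0 lower). Without pro-B replicates 1 and 2, 14 and 8 fragments fell and 2 rose each time. Against pro-B cells 6 fragments rose, in the constant region and both flanks, and 14 fell, of which 12 lay in V regions and 2 in the 3′RR. None passed without either MEF replicate, 27 and 31 did without pro-B replicate 1, 20 and 36 without pro-B replicate 2, and 2 and 6 without resting B replicate 2. Between pro-B cells and MEF 0 of 224 passed by edgeR, and DESeq2 called 3 higher and 4 lower. By edgeR the counts were 6 and 18 without pro-B replicate 1, 8 and 8 without pro-B replicate 2, and 0 and 1 without either resting B replicate. A few pairs took most of these reads, and the top fragment held 41.3% to 83.3% of them per library.

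The gene desert served as a control region. Of its 220 tested pairs, 0 changed between pro-B cells and MEF (75 with an unadjusted p under 0.05, and 16 higher and 40 lower by DESeq2), 1 was lower in resting B cells than in MEF (43 with an unadjusted p under 0.05), and 18 rose and 13 fell in resting B cells against pro-B cells (edgeR quasi-likelihood with Benjamini-Hochberg). In that last comparison 14.1% of the control pairs passed and 7.90% of the Igh pairs, so the number of Igh calls there is not evidence of changes particular to the locus. Leaving out pro-B replicate 1 gave 22 higher and 94 lower for pro-B over MEF, 7 and 44 for resting B over MEF, and 72 and 37 for resting B over pro-B. Leaving out pro-B replicate 2 gave 8 and 42, 7 and 47, and 60 and 48. Without MEF replicates 1 and 2 the falling pairs of resting B over pro-B were 5 and 6, those of resting B over MEF 0 and 2, and those of pro-B over MEF 0 and 10. Without either resting B replicate 0 pairs passed in any of the 3 comparisons. Of its primers, 8 of 24 forward and 13 of 25 reverse ones gave few reads, so the control covered only part of the desert.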

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

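The tests below on very abundant pairs, on copies of V DNA, on silent primers, on the 3′RR contacts of pro-B replicate 1 and on folds that share no library were chosen only after the values they bear on were seen; the other tests were set before. Read pairs that joined primers of the same side, which the alternating design cannot use and the comparisons left out, lay above the limit that a count of 0 allows in each library: 345 and 631 in pro-B replicates 1 and 2, 544 and 1541 in MEF, and 7010 and 11608 in resting B cells.

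Contacts between V fragments were lower in resting B cells than in MEF and pro-B cells, which a few very abundant primer pairs do not account for: with each primer pair counted once on the log scale 8 of the 8 within-region V comparisons stayed lower. Poor capture of a minority of V fragments, such as a strain variant under a primer, is argued against by 91.5% of V fragments (129 of 141) having a median V to V fold below 0 against MEF. Fewer copies of V DNA may contribute. If trans reads follow copies, the folds against MEF argue against copies as the only cause. Trans reads of V fragments lay -0.425 on the log2 scale from those of the constant region (95% bootstrap interval -0.576 to -0.178). The cis difference was -2.18, from a V to V median of -0.958 and a constant region median of 1.23. The bootstrap resamples fragments and leaves out the spread between libraries, so it cannot decide how much copies contribute. Against pro-B cells the trans difference was -0.464 (-1.21 to -0.154) and the cis one -2.05, but the interval reaches past the V to V median of -1.03 and 12 V fragments fell in trans, so copies stay open there as a cause of the V to V fall itself. Also open and untested are a change in folding, a mix of cells with different rearrangements, and the different culture of the cell types.

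The intronic enhancer fragment gained contacts in resting B cells. If trans reads follow copies and capture, more copies or better capture of the fragment is unlikely against MEF. Its trans fold there was -0.01 ± 0.47 (SE) where the median cis fold was 1.65. Against pro-B cells the 13 D-J fragments had a median trans fold of 0.59, with 2 below 0, beside a median cis fold of 1.73. A part played by copies or capture was therefore not excluded in that comparison. Joined V genes alone would give the largest gains with V partners, but the median gain with V partners minus that with 3′ flank and constant region partners was -1.46. A hypothesis left open is a gain in contacts of this enhancer in mature B cells beyond the joined V genes, which the same libraries cannot both raise and test.

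Pro-B replicate 2 stood apart from the other libraries, which sampling of few distinct ligation products could produce: 140 pairs with at least 50 reads in each other library had none in it, against at most 2 in any other library. The share of reads from FOR 451 and REV 300 was 85.8 times the highest share in another library. They were picked as the forward and the reverse primer with the fewest reads in the other libraries, which favours a high ratio. Primers or material carried only by pro-B replicate 2 may add to its difference, but this ratio cannot decide it. That pro-B replicate 1 might instead be an ordinary MEF library under a wrong label is argued against by folds that share no library: pro-B 1 over MEF correlated with pro-B 2 over resting B cells at r = 0.296 (95% bootstrap interval 0.251 to 0.34), where MEF 1 over MEF 2 gave 0.071 (size up to 0.107). The folds of pro-B 1 over MEF 1 and pro-B 2 over MEF 2 correlated at r = 0.172, or 0.201 with the MEF libraries exchanged. Across 3′RR to D-J pairs the median fold of pro-B 1 over MEF was 0.43 (95% bootstrap interval 0.08 to 0.82), against 0.59 between the MEF libraries. Both were scaled to total Igh reads without TMM, and the MEF medians over all Igh pairs were 62 and 104 reads. The 0.59 thus holds an offset between the MEF libraries, so this comparison cannot test the label. By themselves these values did not decide it. A partial mixture with MEF material stays open, and no biological explanation was tested.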

How the results depend on the processing

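The alternatives that average over primer pairs on the log scale, leave out the pair over 500 kb with the most reads (FOR 31 with REV 545), or fit loops with a log-linear model were chosen after seeing the data, and the others before. Of the primer pairs past the threshold, none changed sign under any alternative scaling, filter, tool, block or correction run on all 6 libraries. With 2 libraries per group the counts of calls depended on single libraries, and the cause of each change below was not tested. The fit pooled the spread of all 6 libraries. Chi-square per degree of freedom between replicates was 327 in pro-B cells, 144 in MEF and 72.4 in resting B cells, and this unequal spread was not modelled. With the 4 compared libraries alone, Igh calls were 1656 and 1621 for resting B over MEF and 0 and 0 for resting B over pro-B. Calls of a comparison therefore also depended on the cell type outside it. Where a library was left out, the remaining one of its group was assumed to vary like the other groups. Of the region pairs past the threshold, 0 of 5 (pro-B over MEF), 6 of 27 (resting B over MEF) and 5 of 23 (resting B over pro-B) passed whichever library was left out. Among the latter 5, the 3′RR with near distal V changed sign without FOR 31 with REV 545. The far distal V genes with the 3′ flank and with the constant region, also among them, changed sign under distance correction. The self-test recovered few 4-fold changes of single pairs, so depth and spread limit these counts to large changes.

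For Igh pairs of pro-B over MEF (0 higher, 0 lower), total reads gave 3 and 1, gene desert reads 8 and 2, DESeq2's test 167 and 139, and distance correction 4 higher. Without 1 library the counts ranged from 0 to 1117 higher and from 0 to 2678 lower. For resting B over MEF (44, 46), total reads gave 79 and 89, gene desert reads 86 higher, DESeq2's test 756 and 889, no filter 79 and 77, at least 50 reads 85 lower, distance correction 96 and 101, pairs over 50 kb 0 and 0, and the 4 compared libraries 1656 and 1621. Without 1 library the ranges were 0 to 1642 higher and 0 to 1714 lower. For resting B over pro-B (327, 616), total reads gave 406 lower, gene desert reads 349 lower, DESeq2's test 1303 and 1601, pairs over 50 kb 381 lower, and the 4 compared libraries 0 and 0, with 0 to 3328 higher and 0 to 2210 lower without 1 library.

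For gene desert pairs of pro-B over MEF (0, 0), total reads gave 18 and 21, gene desert reads 20 and 20, and DESeq2's test 16 and 40, with 0 to 22 higher and 0 to 94 lower without 1 library. For resting B over MEF (0, 1), total and gene desert reads gave 0 lower and DESeq2's test 4 and 23, with 0 to 7 and 0 to 47 without 1 library. For resting B over pro-B (18, 13), total reads gave 41 and 23, gene desert reads 40 and 26, and DESeq2's test 53 and 38, with 0 to 72 and 0 to 48.

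With the replicate number as a replicate block, counts changed to 1 higher and 6 lower (Igh pairs, resting B over MEF), 67 and 204 (resting B over pro-B), 2 higher desert pairs (pro-B over MEF), 0 lower desert pairs (resting B over MEF) and 2 lower trans fragments (pro-B over MEF). Among landmark pairs adjusted over the list alone the block gave 8 higher for the 3′RR in pro-B over MEF, 5 lower in resting B over MEF, 4 higher and 13 lower in resting B over pro-B, and 2 and 22 lower for IGCR1 against MEF and pro-B cells. Same-numbered libraries did not deviate together (correlations of -0.04 for pro-B with MEF, 0.08 for pro-B with resting B and -0.01 for MEF with resting B). These values gave no sign of a shared batch, but cannot exclude one whose effect differs by cell type.

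For the intronic enhancer, all counts adjusted over the list alone, pro-B over MEF (0, 0) gave 2 and 2 with total reads, 3 and 2 with gene desert reads, 7 and 5 with DESeq2's test and 6 and 2 with distance correction, with 0 to 16 higher and 0 to 46 lower without 1 library. Resting B over MEF (37, 0) ranged from 4 to 80 higher and 0 to 1 lower without 1 library, and resting B over pro-B (38, 0) from 7 to 84 higher and 0 lower. For the 3′RR, pro-B over MEF (17, 0) gave 1 lower with total and with gene desert reads, 44 and 2 with DESeq2's test and 32 higher with distance correction, with 0 to 68 and 0 to 37 without 1 library. Resting B over MEF (18, 10) gave 6 lower with total reads, gene desert reads and pairs over 50 kb, and 43 and 29 with DESeq2's test, with 0 to 95 and 0 to 49. Resting B over pro-B (17, 66) gave 31 lower with total reads, 30 with gene desert reads, 41 and 104 with DESeq2's test, 10 higher with pairs over 50 kb and 121 lower with distance correction, with 0 to 82 and 0 to 127. For IGCR1, pro-B over MEF (0, 0) gave 6 higher with DESeq2's test, with 0 to 12 and 0 to 13 without 1 library. Resting B over MEF (0, 12) gave 3 higher and 31 lower with DESeq2's test, and 3 lower with total reads, 2 with gene desert reads, 4 with DESeq2's size factors, 23 with at least 50 reads and 4 with distance correction, with 0 to 7 and 0 to 46. Resting B over pro-B (0, 37) gave 24 lower with total reads and 6 with gene desert reads, with 0 to 10 and 0 to 53.

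For region pairs, pro-B over MEF (5, 0) gave 2 and 1 with total reads, 1 higher with gene desert reads, 9 higher with pairs over 50 kb, 1 lower with distance correction, and 10 and 12 with mean logs, with 0 to 19 and 0 to 6 without 1 library. Resting B over MEF (18, 9) gave 5 lower with total reads, 11 and 3 with gene desert reads, 10 and 2 with distance correction and 17 lower with mean logs, with 7 to 27 and 0 to 16. Resting B over pro-B (11, 12) gave 6 lower with total reads, 5 and 5 with gene desert reads, 6 higher with distance correction, and 27 and 19 with mean logs, with 5 to 22 and 0 to 16. Signs turned for 3′RR with near distal V without FOR 31 with REV 545 (-1.16 over MEF, -0.37 over pro-B). With distance correction of resting B over pro-B they turned for the 3′ flank with the 5′ flank (-0.79) and far distal V (-0.23), the constant region with far distal V (-0.00407), and the D-J region with the 5′ flank (-0.71) and far distal V (-0.32). With mean logs they turned for D-J with V-D (0.00514). Under distance correction the change follows from removing each library's decay.

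For fragment trans reads, total trans reads gave 64 higher and 1 lower (pro-B over MEF, 0 and 0), 3 higher (resting B over MEF, 0 and 1) and 0 higher (resting B over pro-B, 6 and 14). The setting with Igh cis reads at separations over 500 kb gave 2 higher, 40 and 34, and 47 and 40. DESeq2's test gave 3 and 4, 0 lower, and 20 and 30. Without 1 library the ranges were 0 to 8 and 0 to 18, 0 to 2 and 0 to 14, and 0 to 27 and 0 to 36. The share of long-range reads in pro-B cells, MEF and resting B cells (43.2%, 44.6% and 54.3%) was 22.6%, 26.0% and 41.6% over 1000 kb, 63.3%, 62.1% and 69.0% over 250 kb, and 10.8%, 8.72% and 15.5% of all Igh reads. It was 43.6% in resting B cells without the 10 pairs with the most reads, and 43.6% without FOR 31 with REV 545, the pair among those 10 that decides it. Loops in resting B cells numbered 9 with separation alone, 143 and 55 at residuals of 1.5 and 3, and 146 in the log-linear model, which gave 134 in MEF. Insulation minima of pro-B cells numbered 2 with a 300 kb window.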

Other observations

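The gain of contacts between the constant side and V genes in resting B cells was graded along the V array. Of 4141 tested primer pairs joining the constant side to V genes, 3 rose and 1 fell past the threshold against MEF. Their median log2 fold was 0.80, so the gradient describes folds that mostly did not pass singly. Taking for each V fragment the median log2 fold over MEF with the 3′ flank, 3′RR, constant and D-J regions, the fragments nearest the D segments had a median of 0.45, those in the middle 0.86 and those farthest away 1.13. A candidate explanation is that V(D)J recombination shortens alleles and brings distal V fragments nearer to the constant region; in a test chosen after the region values were seen, Spearman's rho between position and fold was 0.465 over 140 fragments (permutation p = 0.0001, the smallest the permutations can give). Neighbouring fragments are not independent, so this p is too small, and a different folding of intact alleles in resting B cells would give the same gradient.

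The fragment pair FOR 31 in the 3′RR with REV 545 in the near distal V genes held 22244 and 169302 reads in pro-B replicates 1 and 2, 96787 and 41877 in MEF, and 594468 and 1520284 in resting B cells, 1869 kb apart. FOR 165 (114973711 to 114977500) with REV 819 (117289594 to 117292548), 2315 kb apart, was among the strongest loop calls in each cell type, with 16225 and 16643 reads in resting B cells, 29102 and 19214 in MEF, and 13202 and 78538 in pro-B cells. FOR 36 with REV 810 was high in MEF (19990 and 10483 reads) and lower in resting B cells (2595 and 2278).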
